A study of Anser cygnoides with 6 samples.

How the data were processed

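RNA was sequenced from ovaries of the swan goose, Anser cygnoides, in 2 groups of 3 libraries each. Per the labels, the reproductive group was sampled at the stage of reproduction and the broody group at the stage of broodiness. Broodiness is the phase in which a bird stops laying and sits on eggs, but whether these birds sat on eggs is not known here. The sample titles name the groups R and NR. Per the labels' protocols, the geese were raised to 40 weeks of age in light-controlled housing with 11 h of light and 13 h of dark, and the broody group had undergone forced moulting and short illumination. The labels give the same light programme for all 6 libraries and leave open whether the reproductive group also had short light. Broodiness cannot be separated here from forced moulting, nor from light if it differed. The title and every sample label name ovary, while the design text of the series names oviduct, and a list of oviduct markers was fixed for that reason. Frozen tissue was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The labels give no sequencing batch, no part of the ovary and no statement that the libraries of a group came from separate birds, so p-values measure only the spread among these samples, which may be technical.

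The deposited table holds FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, which the authors computed for 33089 transcripts in each of the 6 libraries. HISAT2, an aligner, and StringTie, an assembler and quantifier, are named without versions, per the submitters' processing notes. The genome build, the annotation release and any strand setting are not given in the sources used here, so no coordinates are printed. Without a strand setting, overlapping antisense genes cannot be told apart, and close paralogs such as the actins and the ribosomal protein genes can share reads. FPKM carry no read counts. No reads were recovered from the values, so the depth of the libraries is unknown and no count model was used. The FPKM of a library summed to between 319866 and 346625, so the values are not TPM.

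Transcripts sharing a gene identifier were summed, which gave 14696 genes. Gene names were taken from the deposited table for 6611 genes and, where it gave none, from a reference table of the assembly Taihu_goose_T2T_genome for 5742 more. That table was used for names only, and 13873 of the gene identifiers occurred in it. The other 2343 genes have no name. Numbers after a gene name are gene identifiers. No pair of libraries shared more than 0.00718% of identical values, so each library counted as 1 sample.

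The 11377 genes with an FPKM of at least 1 in 3 or more of the 6 libraries were tested. A pseudocount of 1 was added, and log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with no covariate. Differences are broody minus reproductive on this scale, with their standard error (SE), and they understate the changes of genes at low FPKM. Two-sided moderated p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Means are of FPKM, with the standard deviation (SD) over the 3 libraries of a group.

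The groups, the test, 32 gene lists and the alternatives were chosen before the data were examined. The lists were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 31 lists with at least 5 tested members. Camera with an estimated correlation, and fry, were run beside it. For each list, members past the threshold were counted over all genes tested and again with p adjusted over the list alone. Named genes followed a rule with 3 parts. The first took the 8 largest increases and the 8 largest decreases among named genes past the threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the groups. The second took 14 fixed reproductive genes, and the third up to 4 members of each list with the smallest p. LHCGR, one of the fixed genes, was not analysed here. Genes named outside the rule are said to be so.

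On simulated data with the means and spread of these libraries, 200 of 11257 genes were changed in a broody minus reproductive comparison. The changed genes were drawn only from those above a limit on mean log2(FPKM + 1), so recovery at low FPKM was not measured. The test recovered 51 of 100 genes changed by 1 on the log2 scale and 87 of 100 changed by 2, each with the right sign, and 2.82% of its calls were false. The simulated noise was independent between genes and few genes were changed, whereas 41.9% of tested genes were called in the data. These rates therefore need not hold for the real comparison. Alternatives covered the pseudocount, the filter on low FPKM, the scaling of the libraries, the fit, the replicate number as a block, the threshold, the lists and each library left out in turn. After the data were seen, the transcript with the highest mean FPKM was tried in place of the sum over transcripts, and a list of mitochondrial ribosomal protein genes was added.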

Results

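The ovary transcriptome was measured in 3 libraries of broody geese and 3 libraries of reproductive geese, as FPKM for 14696 genes. Pearson's r between libraries, across the 11377 genes tested, was 0.972 to 0.980 within the broody group, 0.944 to 0.968 within the reproductive group and 0.812 to 0.947 between the groups. Genes are not independent replicates, and these correlations only describe the libraries. The first principal component held 74.9% of the variance and separated the groups, with scores of -43.9, -44.0 and -26.3 for broody 1 to 3 and 28.8, 67.4 and 18.0 for reproductive 1 to 3. Reproductive 2 lay farthest from the rest. Ribosomal protein genes took 18.4% of its FPKM, against 12.8% in each of the other reproductive libraries and 7.40 to 8.60% in the broody libraries.

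The comparison asked which ovarian transcripts differ between the reproductive and the broody stage. Of the smooth muscle and extracellular matrix genes tested, 14 of 14 and 29 of 36 were lower in the broody ovaries, and of the oocyte and cell cycle genes 24 of 27 and 41 of 55 were higher. Camera called these 4 lists with a preset correlation, but not with an estimated correlation (adjusted p = 0.674 to 0.770), and fry's directional test called none. The smooth muscle genes ACTG2, smooth muscle gamma actin, and MYH11, smooth muscle myosin heavy chain, stood at 288 ± 207 and 1693 ± 901 FPKM (SD, n = 3) in the reproductive group and at 17.6 ± 12.1 and 160 ± 119 FPKM in the broody group. AMH, a hormone of the granulosa cells of small follicles, rose from 57.2 ± 6.33 to 241 ± 47.7 FPKM, and ZP2, a glycoprotein of the egg coat, rose from 147 ± 95.5 to 503 ± 51.7 FPKM. Of the genes tested, 3400 were higher and 1366 lower in broody libraries, by limma with Benjamini-Hochberg adjustment.

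These 4766 genes were 41.9% of those tested, and 71.3% of them were higher in broody libraries. Of these, 1075 were higher and 574 lower by at least 1 on the log2 scale. The 3 libraries of one group lay wholly above those of the other for 59.5% of tested genes, where chance gives 10% on average. Genes measured in the same 6 libraries vary together, so the share can lie far from 10% by chance, and this comparison is no test. The median difference of all tested genes was 0.23, and median-ratio scaling brought it to 0.00. With that scaling 1897 genes were higher and 2136 lower (47.0% higher), with upper-quartile scaling 1776 and 2189 (44.8%), and with quantile normalization 2198 and 1937 (53.2%), so the excess of genes higher in broody depended on the scaling. Without broody 1, and likewise without broody 2, 1 gene passed the threshold (106029546, which has no name), while 4571 and 4686 genes then had an unadjusted p under 0.05. All genes called with 6 libraries kept their sign. For 4729 of them the groups did not overlap, so their sign could not turn when 1 library was left out. The counts of list members past the threshold over all genes tested are 0 without either of these libraries. Those adjusted over the list alone were not computed without them. The scaling alternatives moved the counts of many lists toward lower, and the counts with median-ratio scaling are given below where they differed clearly. Counts of lists without broody 3 are given at the end.

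The 8 largest increases in broody ovaries lay between 2.04 and 2.74 on the log2 scale. FGB (106032371), the beta chain of fibrinogen, had the largest, 2.74 ± 0.43 (SE), with 24.9, 7.61 and 7.07 FPKM in broody 1 to 3 and 0.834 ± 0.327 in the reproductive group. LIMA1 (106047734), an actin-binding protein, rose by 2.17 ± 0.19, from 14.8 ± 3.69 to 69.4 ± 9.14 FPKM. LRP2BP (106035237), which binds a lipoprotein receptor, rose by 2.16, and CCDC60 (106031359) by 2.14. DNAAF8 (106033401), an assembly factor of ciliary dynein arms, rose by 2.08 and GNGT2 (106048321), a G protein gamma subunit, by 2.04. AMH (106045704) rose by 2.05 ± 0.18 and ZP2 (106033326) by 2.04 ± 0.52. Adjusted p of these 8 genes lay between 0.00786 and 0.0239 by limma, and the rule that chose them required no overlap between the groups. LRP2BP and ZP2 missed the threshold without broody 3, with adjusted p of 0.0625 and 0.0581.

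The largest decreases were mostly in genes of muscle. ACTG2 (106047658) had a difference of -3.91 ± 0.66 (SE) and MYH11 (106033446) of -3.52 ± 0.54, and their reproductive means were 16.4 and 10.6 times the broody means. SPEG (106029813), a kinase of the myosin light chain kinase family, fell by 3.44, and CSRP1 (106045887), a LIM domain protein of smooth muscle, fell by 3.35. MUSTN1 (106042823), a small nuclear protein of muscle and skeleton, fell by 3.25. TNC (106037106), the matrix protein tenascin C, fell by 3.21, HSPB1 (106041405), a small heat shock protein, fell by 3.18, and MYL9 (106045436), a regulatory light chain of myosin, fell by 3.17. Adjusted p was between 0.0112 and 0.0149 by limma. The groups did not overlap for any of the 8 genes, as the rule that chose them required. In the broody group, broody 3 had the highest FPKM of each of these genes, such as 296 for MYH11 against 76.3 and 108 in broody 1 and 2.

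**Figure D1:**
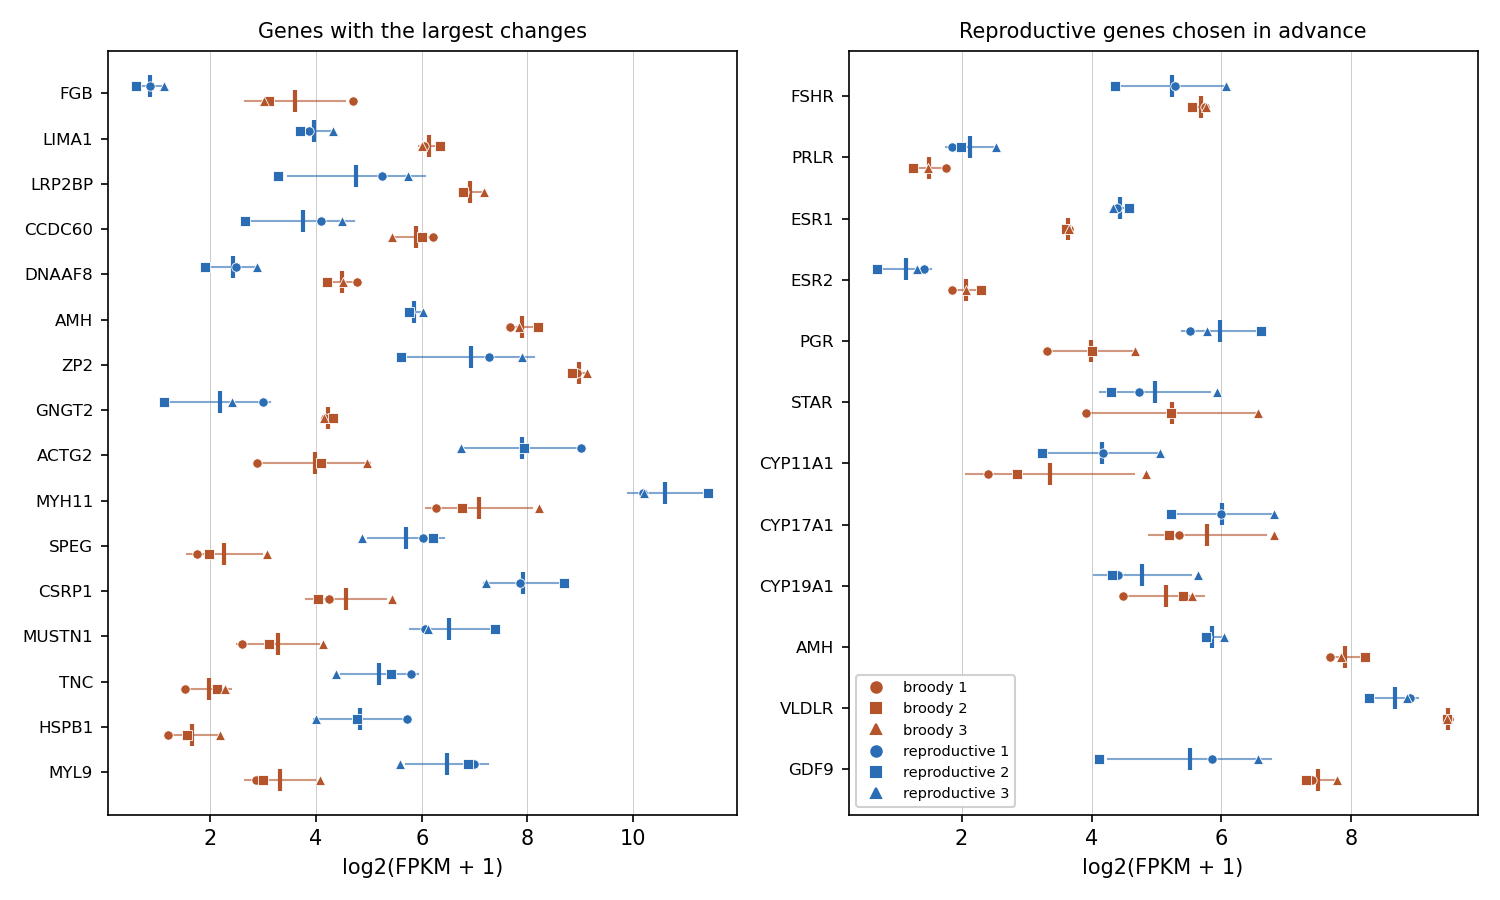
Expression of the named genes as log2(FPKM + 1) on the horizontal axis, with 1 point per library, for the genes with the largest changes (left) and for the 12 reproductive genes chosen in advance that were tested (right). Broody libraries are brown and reproductive libraries blue, vertical ticks are group means and lines are ± 1 SD (n = 3). The groups are apart for all genes on the left, as the rule that chose them required. They overlap for FSHR, STAR, CYP11A1, CYP17A1 and CYP19A1 on the right.

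Of the lists tested, camera called 9, of which 7 were lower and 2 higher in broody libraries. No call held with an estimated inter-gene correlation (smallest adjusted p = 0.674) or with fry's directional test, whereas fry's test for change in either direction called all 31 lists. Smooth muscle markers were the most uniform. All 14 tested members were lower in broody libraries (14 also when adjusted over the list alone), with a median difference of -2.37 and a camera adjusted p of 6.79e-12 (adjusted p = 0.674 with an estimated correlation). MYLK, the kinase that starts smooth muscle contraction, fell from 678 ± 226 to 77.7 ± 39.3 FPKM, and TPM1, an alpha tropomyosin, fell from 690 ± 247 to 109 ± 38.7 FPKM.

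Extracellular matrix genes were mostly lower too. Of 36 tested, 29 were lower and 1 higher (29 and 1 adjusted over the list alone), with a median of -1.59 and an adjusted p of 7.46e-17 (adjusted p = 0.674 with an estimated correlation). COL6A1 and COL6A2, chains of collagen VI, differed by -2.84 and -2.67, and OGN, the small proteoglycan osteoglycin, by -2.39. The member that rose, LAMA1, a laminin chain of basement membranes, was named for its opposite direction and went from 13.5 to 31.1 FPKM. Among theca cell markers, genes of the outer follicle wall, 5 of 13 were lower and 0 higher (5 and 0 adjusted over the list alone), with a median of -0.78 and an adjusted p of 0.00180 (adjusted p = 0.674 with an estimated correlation). With no filter the median over 15 genes was -0.26 (adjusted p = 0.0158). The lower members included DCN, the proteoglycan decorin, also on the matrix list, which fell by 1.49 from 568 ± 172 FPKM. COLEC11, a collectin, fell by 1.36. CYP17A1, CYP19A1 and STAR, steroidogenic genes of the same list, did not pass, with differences of -0.22, 0.36 and 0.25. The median FPKM of the list overlapped between the groups, at 14.2 to 31.7 in broody and 18.9 to 41.8 in reproductive libraries. Endothelial markers were lower for 8 of 13 genes and higher for 1 (9 and 1 adjusted over the list alone), with a median of -0.70 and an adjusted p of 4.70e-05 (adjusted p = 0.716 with an estimated correlation). VWF, von Willebrand factor, fell from 63.4 ± 12.9 to 17.2 ± 4.73 FPKM and PECAM1 from 54.8 ± 8.80 to 29.2 ± 2.24 FPKM, while EGFL7, named for its opposite direction, rose by 0.48. That rise missed the threshold with median-ratio, upper-quartile and quantile scaling, with no filter, with the replicate block and without broody 3, reproductive 1 or reproductive 2. Without reproductive 2 the list had 5 lower.

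Macrophage and granulocyte markers were lower for 15 of 17 genes and higher for 0 (15 and 0 adjusted over the list alone). Their median was -1.47 and the camera adjusted p was 1.30e-10 (adjusted p = 0.674 with an estimated correlation). MPEG1, a pore-forming protein of macrophages, fell from 13.3 ± 2.99 to 1.82 ± 0.480 FPKM, with a limma adjusted p of 0.00786. SPI1, a transcription factor of myeloid cells, fell by 1.93 and LY86 by 1.69. T and B cell markers were not called (adjusted p = 0.135, median -0.18), with 4 of 13 lower and 1 higher (3 and 1 adjusted over the list alone). Among them CD2, a surface protein of T cells, fell by 1.26, and the list was called without broody 3 (adjusted p = 0.0149), whereas its median turned to 0.09 without broody 2 (adjusted p = 0.352) and to 0.01 without reproductive 3 (adjusted p = 0.221). Interferon and inflammatory genes had 3 higher and 3 lower of 18 (3 and 3 adjusted over the list alone), or 1 and 6 with median-ratio scaling, a median of -0.12 (-0.36 with that scaling) and an adjusted p of 0.125. Without reproductive 1 these were -0.30 and 0.0290. TRIM25, a ubiquitin ligase of antiviral signalling, fell by 0.90 and NFKBIA, an inhibitor of NF-kappaB, fell by 0.68, while SOCS1 rose by 1.08 and CMPK2 by 0.76.

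Cytosolic ribosomal protein genes were lower for 41 of 57 members and higher for 1 (50 and 1 adjusted over the list alone). The median was -0.86 and the adjusted p was 4.05e-19 (adjusted p = 0.674 with an estimated correlation). RPS6 went from 194 ± 41.3 to 70.8 ± 14.9 FPKM, RPL29 from 515 ± 160 to 183 ± 17.2 and RPS15 from 240 ± 46.3 to 113 ± 15.9. The member that rose was RPS20, named for its direction, with a difference of 0.49 that missed the threshold with median-ratio and upper-quartile scaling, with the replicate block and without broody 3. With quantile normalization the median was -0.30 and 18 members were lower. The lower members were 15 with the replicate block, 26 with no filter and 26 without broody 3, and the list was still called in each case. The oxidative phosphorylation list, the respiratory chain and its ATP synthase, was not called (adjusted p = 0.567). Of 51 members 9 were higher and 5 lower (2 and 3 adjusted over the list alone). With median-ratio scaling the balance reversed to 1 higher and 11 lower, and the median of 0.11 turned to -0.12. The counts were 1 and 2 with the replicate block, and the median was 0.04 without reproductive 2. COX5A rose by 1.25 and COX6C fell by 0.69.

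Oocyte and germ cell markers were higher in broody libraries for 24 of 27 members and lower for 1 (25 and 1 adjusted over the list alone), or 18 and 1 with median-ratio and 16 and 1 with upper-quartile scaling. They were 9 and 1 without broody 3 and 16 and 1 without reproductive 1. The median was 1.38 and the camera adjusted p was 0.000353 (adjusted p = 0.770 with an estimated correlation). ASZ1, a germ cell protein that guards against transposons, rose from 2.58 ± 0.931 to 11.2 ± 1.30 FPKM, and WEE2, an oocyte kinase that holds meiosis arrested, rose from 61.5 ± 26.1 to 152 ± 4.94 FPKM. RNF17, a Tudor domain protein of germ cells, rose by 1.41. ZP1, an egg coat glycoprotein that birds make mainly in the liver, went the other way, from 3.19 ± 0.778 to 0.275 ± 0.203 FPKM. Reproductive 2 had the lowest oocyte median, 3.33 FPKM against 7.86 and 8.97 in the other reproductive libraries and 14.4 to 19.0 in broody libraries, and the highest ribosomal median, 1012 FPKM against 419 to 710 elsewhere.

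Cell cycle genes were higher for 41 of 55 members and lower for 1 (46 and 3 adjusted over the list alone), or 30 and 4 with median-ratio scaling and 20 and 0 without broody 3, with a median of 0.94 and an adjusted p of 2.40e-05 (adjusted p = 0.770 with an estimated correlation). E2F1, a transcription factor of S phase entry, rose from 6.83 ± 1.34 to 13.9 ± 0.940 FPKM, NCAPG, a condensin subunit, rose by 1.34, and PLK4, the kinase of centriole duplication, rose from 8.24 ± 3.64 to 23.7 ± 1.66 FPKM. CCND1, a G1 cyclin, was the member that fell, from 12.4 to 5.92 FPKM, and is named for that direction. Immediate early and heat shock genes were called as lower (adjusted p = 0.0157, and adjusted p = 0.770 with an estimated correlation), with 9 lower and 3 higher of 28 (10 and 3 adjusted over the list alone, and 12 and 0 over all genes with median-ratio scaling) and a median of -0.18. KLF6 and KLF2, zinc finger factors, fell by 1.23 and 1.12 and the chaperone DNAJB4 fell by 1.36. This call ended without reproductive 1 (adjusted p = 0.142), where the median shrank to -0.05 with 6 higher and 6 lower, and with quantile normalization (adjusted p = 0.0688), where it grew to -0.43 with 1 higher and 13 lower.

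**Figure D2:**
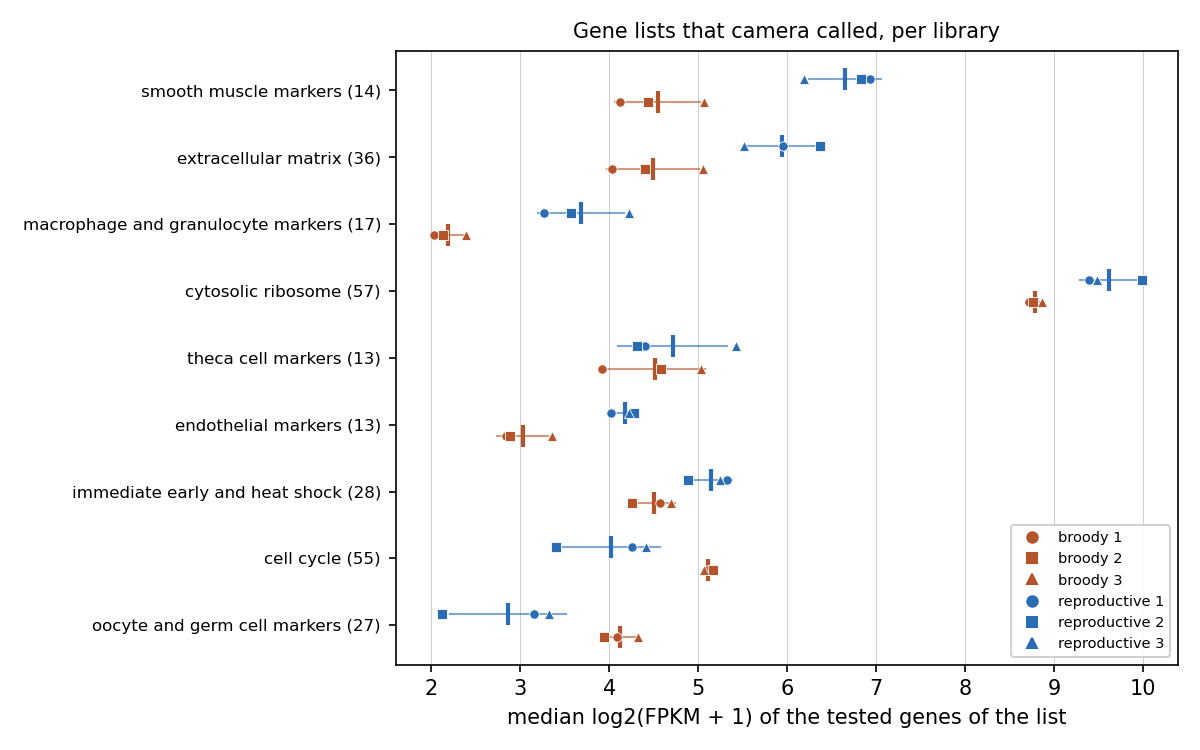
Median log2(FPKM + 1) over the tested genes of each list (horizontal axis, gene number in brackets) for the 9 lists camera called, with 1 point per library (broody brown, reproductive blue), group means as vertical ticks and ± 1 SD as lines (n = 3). Smooth muscle medians lay between 4.12 and 5.07 in broody libraries and between 6.19 and 6.93 in reproductive libraries, and oocyte medians lay between 3.94 and 4.32 and between 2.11 and 3.32.

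Steroid hormone genes were not called as a group. Of 18 tested, 5 were higher and 2 lower (5 and 2 adjusted over the list alone), or 4 and 3 with median-ratio scaling, and the camera adjusted p was 0.981. The median of 0.26 was 0.01 with median-ratio scaling, 0.07 with no filter, 0.07 without reproductive 2 and 0.11 without broody 3, and turned negative, to -0.00474, with upper-quartile scaling. STAR, which carries cholesterol into mitochondria, had 48.0 ± 41.1 FPKM in broody and 34.6 ± 22.1 in reproductive libraries, a difference of 0.25 ± 0.67 (SE). CYP11A1, the first enzyme of steroid synthesis, had 12.7 ± 12.9 against 19.2 ± 12.0 FPKM (-0.79 ± 0.68), CYP17A1, the enzyme toward androgens, 62.2 ± 42.8 against 69.9 ± 37.8 FPKM (-0.22 ± 0.52), and CYP19A1, the aromatase, 36.3 ± 13.1 against 29.3 ± 16.9 FPKM (0.36 ± 0.41). Adjusted p of these 4 genes was 0.362 to 0.774 by limma, so their differences did not exceed the spread between libraries. NR5A1, a transcription factor of steroid-making cells, rose by 1.15, SRD5A1, a 5-alpha reductase, by 1.13 and HSD17B2, which inactivates estradiol, by 0.96. The genes that fell, named after their values were seen, were NR5A2 (by 0.47) and HSD3B1, the enzyme that makes progesterone (by 1.16).

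Of 22 hormone receptors tested, 4 were higher and 5 lower (4 and 5 adjusted over the list alone), with an adjusted p of 0.135 and a median of 0.04. With median-ratio scaling 1 was higher and 7 lower, and the median was -0.19, and without broody 3 these were 0, 6 and -0.05 (adjusted p = 0.0714). PGR, the progesterone receptor, went from 65.2 ± 27.9 to 16.1 ± 7.78 FPKM (limma adjusted p = 0.0172), ESR1, estrogen receptor alpha, from 20.6 ± 1.87 to 11.4 ± 0.227 (adjusted p = 0.0138) and VIPR2, a receptor of vasoactive intestinal peptide, from 84.7 ± 24.0 to 15.2 ± 7.93 (adjusted p = 0.0129). ESR2, estrogen receptor beta, rose from 1.26 ± 0.559 to 3.23 ± 0.659 FPKM (adjusted p = 0.0223, and 0.0523 without broody 3). FSHR, the receptor of follicle-stimulating hormone, had 50.6 ± 4.09 FPKM in broody and 41.3 ± 23.7 in reproductive libraries (adjusted p = 0.364), and it passed without reproductive 3 (difference 0.86, adjusted p = 0.0440). PRLR, the receptor of prolactin, the hormone of broodiness, had 1.86 ± 0.504 against 3.45 ± 1.16 FPKM, a difference of -0.62 that missed the threshold (adjusted p = 0.0607). It passed with median-ratio scaling (-0.80, adjusted p = 0.0274), upper-quartile scaling (-0.81, adjusted p = 0.0284) and quantile normalization (-0.74, adjusted p = 0.0312). INHA was listed between 0 and 0.0472 FPKM in the 6 libraries and was not tested.

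Granulosa cell markers were higher for 7 of 16 members and lower for 2 (7 and 2 adjusted over the list alone), or 5 and 4 with median-ratio scaling, with a median of 0.64 (0.39 with that scaling) and an adjusted p of 0.427. Beside AMH, FOXL2, a transcription factor of granulosa cells, rose from 26.9 ± 10.7 to 75.7 ± 9.97 FPKM and CDH2, N-cadherin, from 21.7 ± 7.79 to 54.8 ± 6.35. Of 31 genes of the TGF-beta family, 7 were higher and 5 lower (7 and 3 adjusted over the list alone), with an adjusted p of 0.757 and a median of 0.16. With median-ratio scaling 6 were higher and 8 lower, and the median was -0.09. Leaving out each library in turn gave up to 11 higher and up to 4 lower. GDF9 and BMP15, growth factors secreted by the oocyte, rose by 1.98 ± 0.55 (limma adjusted p = 0.0283) and 1.27 ± 0.30, whereas TGFB3 fell by 1.34. GDF9 missed the threshold without broody 3 (adjusted p = 0.0736), without reproductive 1 (0.0522) and with the highest transcript in place of the sum (0.0517). Ovulation and prostaglandin genes had 4 higher and 5 lower of 19 (4 and 5 adjusted over the list alone), or 3 and 6 with median-ratio scaling, a median of -0.23 and an adjusted p of 0.135. The median was -0.48 with median-ratio scaling and also without reproductive 1 (adjusted p = 0.0523). ADAMTS1, a protease of ovulating follicles, fell by 0.75 and PTGES3, a prostaglandin E synthase, rose by 0.83.

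Genes of yolk uptake were higher for 9 of 24 members and lower for 0 (11 and 1 adjusted over the list alone), but for 6 and 5 with median-ratio scaling, with a median of 0.45 (0.19 with that scaling) and an adjusted p of 0.259. VLDLR, the oocyte receptor for yolk precursors, had 713 ± 8.66 against 414 ± 92.6 FPKM, a rise of 0.81 ± 0.22 (limma adjusted p = 0.0266). That call ended with median-ratio scaling (0.55, adjusted p = 0.0713), upper-quartile scaling (0.54, adjusted p = 0.0765), no filter (adjusted p = 0.0531) and without broody 3 (adjusted p = 0.0636). DAB2, an endocytic adaptor, rose by 1.46 and RAB5C, a GTPase of early endosomes, by 1.04. Cholesterol synthesis and uptake genes were higher for 10 of 24 and lower for 0 (10 and 0 adjusted over the list alone), or 5 and 0 with median-ratio scaling, with a median of 0.55 and an adjusted p of 0.158. Without reproductive 1 these were 0.74 and 0.0215, without reproductive 2 0.33 and 0.338, and with median-ratio scaling 0.31 and 0.141. Without reproductive 2, 6 were higher. NPC1, a lysosomal cholesterol transporter, rose from 107 ± 29.5 to 279 ± 47.2 FPKM, and SOAT1, which esterifies cholesterol, rose by 1.18. Lipogenesis genes were higher for 7 of 20 and lower for 1 (8 and 1 adjusted over the list alone), or 5 and 1 with median-ratio and 4 and 1 with upper-quartile scaling, with a median of 0.34 (0.09 with median-ratio scaling) and an adjusted p of 0.285. SCD, the stearoyl-CoA desaturase, rose by 1.15 and DGAT2, of triglyceride synthesis, by 1.45, while FADS2, a fatty acid desaturase named for its opposite direction, fell by 1.09. Genes of lipid catabolism and fasting had 5 higher and 4 lower of 29 (3 and 2 adjusted over the list alone), or 3 and 8 with median-ratio scaling, a median of -0.01 (-0.19 with that scaling, 0.12 without reproductive 3) and an adjusted p of 0.317. PPARGC1A, a coactivator of mitochondrial genes, rose by 1.21.

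The insulin-like growth factor axis had 8 higher and 6 lower of 30 (8 and 7 adjusted over the list alone), or 4 and 9 with median-ratio scaling, a median of 0.24 (0.05 with that scaling) and an adjusted p of 0.468. IGF1 itself fell from 21.1 ± 6.82 to 3.21 ± 1.79 FPKM. Autophagy and lysosome genes had 7 higher and 7 lower of 43 (6 and 7 adjusted over the list alone), an adjusted p of 0.567 and a median of 0.20. With median-ratio scaling 3 were higher and 13 lower, and the median was -0.04. It was 0.134 without reproductive 1 and 0.125 without reproductive 2. CTSK, a collagen-degrading cathepsin, fell from 145 ± 52.9 to 19.1 ± 13.8 FPKM and WIPI2, of early autophagosomes, rose by 0.84. Apoptosis genes had 6 higher and 3 lower of 27 (6 and 3 adjusted over the list alone), or 2 and 5 with median-ratio scaling, a median of -0.04 (-0.28 with that scaling, 0.08 without broody 2) and an adjusted p of 0.427. FAS, a death receptor, fell by 1.01 and CIDEA rose by 1.04. Antioxidant genes had 7 higher and 3 lower of 30 (7 and 3 adjusted over the list alone), an adjusted p of 0.468 and a median of 0.07. With median-ratio scaling 2 were higher and 6 lower, and the median was -0.16. Without broody 3 the median was 0.14, and without reproductive 1 the counts were 4 and 5. HMOX1, heme oxygenase 1, fell by 1.70 and SOD3, the extracellular superoxide dismutase, by 1.61, while GSTO1 rose by 1.34. Circadian clock genes had 4 higher and 2 lower of 20 (1 and 0 adjusted over the list alone), or 1 and 5 with median-ratio scaling, a median of -0.00207 (-0.19 with that scaling, 0.13 without reproductive 2) and an adjusted p of 0.455. CRY1, a repressor of the clock, rose by 0.79, a call that ended with the highest transcript in place of the sum (adjusted p = 0.103). The mean difference or the median had another sign than the camera direction for the lists of steroid hormones, hormone receptors, TGF-beta, apoptosis, autophagy, lipid catabolism, clock, antioxidant, respiratory chain and insulin-like growth factor genes, none of which camera called.

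Markers of other tissues were tested as well. Liver genes and yolk proteins were higher for 7 of 11 members and lower for 1 (7 and 1 adjusted over the list alone), with a median of 1.13 and an adjusted p of 0.265. With no filter the median over 18 genes was 0.23, and with a pseudocount of 0.1 it was 1.72. Beside FGB, APOH, a plasma apolipoprotein, rose from 1.89 ± 0.589 to 6.37 ± 0.548 FPKM and ITIH2, a plasma protease inhibitor chain, rose from 0.657 ± 0.391 to 2.59 ± 0.501. SERPINC1, antithrombin, named for its opposite direction, fell by 0.54. Ciliated epithelium markers had 8 higher and 1 lower of 20 (8 and 1 adjusted over the list alone), a median of 0.30 (0.11 with median-ratio scaling) and an adjusted p of 0.338. CCDC40, needed for the beating of cilia, rose by 0.98, while TPPP3, a tubulin-binding protein, fell by 1.99. Epithelial markers had 4 higher and 0 lower of 7 (4 and 0 adjusted over the list alone), a median of 1.13 and an adjusted p of 0.317. That median was 0.69 without reproductive 2 and 0.30 over 14 genes with no filter. ESRP1, a splicing factor of epithelia, was higher by 1.46. Erythrocyte markers had 2 higher and 0 lower of 7 (2 and 0 adjusted over the list alone), or 1 and 1 with median-ratio scaling, a median of 0.57 and an adjusted p of 0.753. The median was 0.33 with median-ratio scaling, 0.27 without reproductive 1, 0.27 without reproductive 2 and 0.06 over 9 genes with no filter. RHAG, of the red cell membrane, was 1 of those higher, with a rise of 1.49 that missed the threshold without broody 3 (adjusted p = 0.0607). Adrenal markers had 2 higher and 1 lower of 6 (2 and 1 adjusted over the list alone), or 1 and 1 with median-ratio scaling, a median of 0.49 and an adjusted p of 0.753. The median was 0.28 with median-ratio scaling, 0.19 without reproductive 1 and -0.02 over 12 genes with no filter. SLC18A2, a vesicular amine transporter, was higher by 1.16. Of 8 oviduct secretory markers with values, 2 reached the filter, too few for a list test, and neither passed (0 higher and 0 lower, also adjusted over the list alone). TF, the egg white protein ovotransferrin, was at 71.1 FPKM in reproductive 2 and at 0.969 to 4.79 FPKM in the other libraries.

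Without broody 3, 3003 genes passed, and the counts of many lists fell. Higher and lower members were then 4 and 0 for cholesterol, 5 and 0 for yolk uptake, 4 and 3 for oxidative phosphorylation, 3 and 3 for antioxidant genes, 2 and 3 for apoptosis and 2 and 5 for autophagy. They were 2 and 0 for lipid catabolism, 1 and 2 for ovulation, 1 and 2 for interferon genes, 5 and 5 for the insulin-like growth factor axis, 5 and 3 for TGF-beta, 3 and 0 for the clock and 0 and 7 for immediate early genes. Steroid hormone genes had 4 and 1, granulosa markers 5 and 0, T and B cell markers 0 and 4, epithelial markers 2 and 0, adrenal markers 1 and 1, erythrocyte markers 0 and 0, lipogenesis 5 and 1 and liver markers 7 and 0. With the replicate block, counts were 6 and 0 for cholesterol, 6 and 0 for yolk uptake, 3 and 4 for autophagy, 2 and 3 for hormone receptors, 3 and 3 for antioxidant genes, 4 and 0 for lipogenesis and 1 and 4 for immediate early genes.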

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

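The highest-transcript setting was chosen after the data were seen. The number of genes past the threshold (4766, with 3400 higher and 1366 lower in broody libraries) stayed within 1.5 times under the other pseudocounts, filters, scalings and fits, from 3913 to 5401. Scaling moved its parts, to 1897 higher and 2136 lower with median-ratio scaling, 1776 and 2189 with upper-quartile scaling and 2198 higher with quantile normalization. It fell to 3147 (2180 higher) with the highest transcript, where 85 genes called with the sum turned sign, to 1649 (1075 and 574) with a log2 difference of at least 1 added to the threshold, and to 1727 (1122 and 605) with that limit and an unadjusted p. Leaving out each library gave 1 to 4950 genes, 0 to 3765 higher and 1 to 1225 lower. It was 1 without broody 1 and 1 without broody 2, where the next smallest adjusted p was 0.0508 and 0.0572 and 3799 and 3979 genes lay under 0.10, against 3003 without broody 3 and 3528 to 4950 without a reproductive library. Those fits had fewer samples, but why these broody libraries mattered most was not tested. The correlation across genes of their differences with those from 6 libraries was 0.976 to 0.991, though these fits share most of their libraries with the full fit. With the replicate number as a block, 3173 genes passed (2225 higher). Same-numbered libraries deviated from their group means with correlations of 0.11, -0.158 and -0.203 across genes. Pairs with other numbers gave -0.177 to 0.291. These values show no sign of pairing by number, but so few libraries cannot exclude it, and the labels do not say.

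Of the 142 named genes tested, 131 were called and none of these turned direction under any alternative. All 131 missed the threshold without broody 1 and without broody 2, and at most 18 did under any other setting. STAR turned to -0.00569 with upper-quartile scaling and -0.10 with library weights, and ranged from -0.41 to 0.91 without each library. CYP17A1 ranged from -0.74 to 0.18. EPB41 was 0.12 with the highest transcript. TGM4 was -0.13, -0.14, -0.0768, -0.0634 and -0.15 with median-ratio scaling, upper-quartile scaling, quantile normalization, library weights and the highest transcript, and ranged from -0.38 to 0.33 without each library. The 9 lists camera called were all called with ranks, without shared members, with a pseudocount of 0.1, with no filter, with median-ratio scaling and with the block, and 8 with quantile normalization. List directions turned only for lists that camera had not called, with adjusted p of 0.382 (steroid), 0.114 (TGF-beta), 0.530 (apoptosis), 0.494 (autophagy), 0.724 (lipid catabolism), 0.568 (clock), 0.507 (antioxidant) and 0.305 (respiratory chain and insulin-like growth factor) by fry, which does not compare a list with other genes. Others were 0.454 (steroid) without shared members, 0.937 (TGF-beta), 0.906 (erythrocyte) and 0.801 (adrenal) with no filter and 0.973 (steroid) with median-ratio scaling. Without each library, adjusted p ranged from 0.661 to 0.995 for the steroid list, 0.425 to 0.995 for the adrenal list and 0.662 to 0.924 for the TGF-beta list. The cause of these turns was not tested. Depth is unknown, so no limit from counting can be given.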

Other observations

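The tests of the mitochondrial ribosome, of single genes and of the explanations below were chosen after the results were seen, except the count over other splits of the libraries. Genes of the mitochondrial ribosome, which makes proteins of the respiratory chain, did not follow those of the cytosolic ribosome. Of 59 tested, 23 were higher and 3 lower in broody libraries, with a median of 0.35 (camera p = 0.00857, and p = 0.405 with an estimated correlation) against a median of 0.23 for all tested genes. Of all 11377 genes tested, 3400 were higher and 1366 lower. These camera p-values were not adjusted over the lists, and no other scaling was run for this list. MRPS5 went from 5.62 ± 1.04 to 14.6 ± 0.545 FPKM (SD, n = 3), and MRPL47 from 47.9 ± 15.9 to 98.6 ± 12.6 FPKM. The unnamed gene 106029546, with 1 transcript, was listed at 0 in the 3 broody libraries and at 16.5, 26.2 and 14.9 FPKM in reproductive 1 to 3 (limma adjusted p = 0.00122). STAR, CYP11A1, CYP17A1 and CYP19A1 were each highest in broody 3 within their group (93.8, 27.6, 111.6 and 45.9 FPKM) and in reproductive 3 within theirs (59.8, 32.2, 110.8 and 48.8 FPKM).

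A few genes were abundant in 1 library, with at least 5 FPKM and 10 times the next highest library. Reproductive 2 held 4 of these 7 genes. They were TF, ovotransferrin, STMN2, a microtubule regulator of neurons, at 14.8 FPKM against 1.22 or less elsewhere, and the unnamed genes 106032443 and 106032431, at 60.7 and 22.2 FPKM against 0.145 and 0.481 or less. UTS2B, a urotensin-related peptide hormone, was at 39.4 FPKM in reproductive 1 and at 1.21 or less elsewhere. The unnamed gene 106029425 was at 279 FPKM in reproductive 3 and at 2.51 or less elsewhere, and 106049217 was at 5.86 FPKM in broody 2 and at 0.512 or less elsewhere. PIGR, which carries antibodies across epithelia and was on the oviduct list, was at 3.55 FPKM in reproductive 2 and at 0.104 or less elsewhere.

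The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4766 genes past the threshold, and the highest of the other splits gave 0, so 1 of the 10 splits gave as many. For gene lists, camera with the preset correlation called 9 lists in the real split and up to 13 in another, and 6 of the 10 splits called at least 9. Camera with the preset correlation thus called lists in splits that mix the groups as well.

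Oocyte markers were higher and smooth muscle markers lower in broody libraries. A single dilution of all follicle transcripts by other tissue would move steroidogenic genes with the oocyte genes. The median of STAR, CYP11A1, HSD3B1, CYP17A1 and CYP19A1 was -0.225 (-0.74 to 0.18 without each library), below the oocyte median of 1.38 (0.96 to 1.68). These genes varied widely within groups, such as STAR from 14.2 to 93.8 FPKM in broody libraries, so this is a weak test. Granulosa markers had a median of 0.64 and theca markers of -0.78, and a dilution of only a part of the follicle was not tested. One common loss of all tissue around the follicles would lower endothelial genes as far as muscle genes, if both came only from that tissue, which was not tested. Their medians were -0.70 (-0.78 to -0.53) and -2.37 (-2.67 to -2.03). Extracellular matrix and macrophage medians lay between them, at -1.59 and -1.47. The unequal falls therefore do not exclude a loss of such tissue. Under 4 other scalings the oocyte median was at least 1.11 and the muscle median at most -2.40. A scale factor per library moves both lists alike, so it could not have set them apart, and scalings of that kind are no test of the gap. Quantile normalization, which is not such a factor but keeps the order of genes within a library, gave 1.15 and -2.40. That argues against a rescaling that keeps this order as the source of the gap, and tests no other bias. More muscle in the pieces of reproductive ovary that were taken cannot be told apart from a change with broodiness, since the labels give no part of the ovary. The muscle median ranged over 0.742 on the log2 scale among the reproductive libraries. A difference between the reproductive and the broody group in follicle makeup, or in the effects of forced moulting or light, stays open as well.

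Cytosolic ribosomal protein genes were lower in broody libraries. If 1 scale factor per library, set by a few abundant genes, had made the pattern, median-ratio or upper-quartile scaling would bring the ribosomal median of -0.86 near 0. It went to -1.12 and -1.13. Such a factor moves all genes alike, so this shift followed from the median of all tested genes, 0.23, and is no separate test. Relative to that median the ribosomal genes stood at -1.09 on the deposited scale and at -1.12 with either scaling. A bias that grows with abundance stays open, since quantile normalization cut the median to -0.30 and the lower members from 41 to 18. A single library is argued against by a median of -0.659 or lower without each library, closest to 0 without reproductive 2. Transcript lengths were not used here, so a loss of short transcripts, a different mix of cell types and a change with broodiness all stay open.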
